A study of Caenorhabditis elegans with 34 samples.

How the data were processed

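The series measured polyadenylated RNA of Caenorhabditis elegans by paired-end sequencing in a strain that carries green fluorescent protein (GFP) fused to a histone under the elt-2 promoter, which is active in the intestine. Animals were taken as mixed embryos, first-stage larvae (L1) and third-stage larvae (L3). At each stage 4 fractions were profiled: whole animals, dissociated unsorted cells, and cells sorted as GFP-positive or GFP-negative. The labels describe 34 libraries as biological replicates. The tables hold columns for 30 of them, and the 4 libraries of L1 replicate 2 were not analysed here. The 12 groups of stage and fraction held 2 or 3 libraries each. All L1 groups, embryo whole animals and embryo dissociated cells had 2 libraries, and the other groups had 3. L1 replicate 1 was sequenced on a HiSeq X-ten and L1 replicate 3 on another instrument model, per the labels' protocols, so replicate and sequencer cannot be told apart within L1. All embryo and L3 libraries were sequenced on the same model as L1 replicate 3.

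The submitters' processing notes list fastp 0.20.0, HISAT2 2.1.0, featureCounts 1.6.4, SAMtools 1.9, deepTools 3.2.0, DESeq2 1.28.1 and the genome build ce11, with no role or order. The deposited count table holds whole-number raw counts per gene in 16762 rows, with a lowest row total of 75. The rule by which the authors chose these rows is not given in the sources used here, nor are the counting options, so reads of overlapping, antisense or near-identical genes could be split in unknown ways. The deposited normalized table is a signal equal to the raw counts times 1 constant per library. The largest relative deviation from that constant was 5e-07, and the implied factors correlated at r = 0.9999 across the 30 libraries with DESeq2 size factors computed here, which share their origin in the same counts. The third deposited table holds log2-scale values that its name calls rlog. It served only to compare replicates and principal components with those of the counts.

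The rows of the expression tables used here carry no gene identifier, and the files do not pair rows with genes. No row was matched to a gene by its position. The 33 gene lists fixed before the data were examined, their tests and the rule for named genes could therefore not be applied. Gene groups defined by the comparisons themselves took their place, and they were devised after the data were seen. For each stage, a higher set and a lower set were formed from the genes called higher, or lower, in GFP-positive than in GFP-negative cells at both other stages. These sets share no library with the stage in which they were then measured. The genes called higher at all 3 stages are referred to as the shared GFP-positive genes. Single rows are named by their number in the table, as the 2 highest and the 2 lowest log2 fold changes among called genes of the embryo sort with a mean of at least 10 CPM over the compared libraries. That choice adapts the earlier rule and was made after the data were seen.

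Raw counts were tested with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr with a minimum count of 10, which left 16758 genes. Libraries were scaled by TMM, and 1 quasi-likelihood model with 1 mean per group was fitted to all 30 libraries, giving 18 residual degrees of freedom. The design planned before the data were examined had assumed all 34 libraries. Each of the 13 comparisons was a two-sided quasi-likelihood F-test with Benjamini-Hochberg adjustment over all tested genes, and a gene is called here at an adjusted p under 0.05. Sets were tested with camera in limma 3.58.1 at a preset inter-gene correlation of 0.01, again with an estimated correlation, and with fry, each adjusted over the 18 set tests. Shares of counts were computed from raw counts, and log2 CPM used a prior count of 2.

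The procedure was tested on simulated data with the real library sizes and 1 dispersion per gene, shared by all groups. At each stage the real means were averaged over GFP-positive and GFP-negative cells, and over dissociated cells and whole animals. Then 200 of 16758 genes were changed by 2-fold or 4-fold in each of 6 comparisons. In the embryo sort 39% of the 4-fold and 5% of the 2-fold changes were called. In the L1 sort the shares were 27% and 1%, and in the L3 sort 38% and 2%. For dissociation, 16% of the 4-fold changes were called in embryo, 20% in L1 and 44% in L3. Of the called genes, at most 9.7% were unchanged ones, in the L1 sort. Few genes changed in this simulation, so its threshold was stricter than in the real sorts. Spread that differs between groups was not simulated, so these shares may not hold where real groups vary unequally.

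Library totals ran from 10994387 to 49400873 counts. Replicates of every group differed by far more than sampling noise, with a chi-square per degree of freedom of at least 34.7. In the GFP-positive and GFP-negative libraries of equal number, deviations from the group means correlated across genes at 0.28, 0.26 and 0.16 in embryo and at 0.18, 0.19 and 0.24 in L3, so these numbers were taken as pairs. The main model had no replicate block. Alternatives comprised other scalings, filters, tools and thresholds, a fit of only the compared groups, a replicate block, a sequencer term, and each library left out in turn. The deposited size factors, a CPM filter, thinning to equal depth and removal of the gene with the largest share were chosen after seeing the data.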

Results

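RNA was profiled in 30 libraries from 3 stages of C. elegans, to describe the transcriptome of intestinal cells marked by GFP under the promoter of elt-2, which encodes an intestinal GATA transcription factor. Sorted GFP-negative cells, unsorted dissociated cells and whole animals served as comparators. Totals ranged from 20252498 to 49400873 counts in embryo, from 14608535 to 49077624 in L1 and from 10994387 to 26523420 in L3. The lowest total belonged to GFP-positive L3 cells. Genes with at least 1 CPM numbered 11110 ± 514 (SD, n = 3) in embryo GFP-positive cells, 11658 ± 433 (SD, n = 2) in L1 and 12842 ± 266 (SD, n = 3) in L3. Whole animals had 12614 ± 390 (SD, n = 2) in embryo, 13870 ± 97 (SD, n = 2) in L1 and 12803 ± 77 (SD, n = 3) in L3.

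The first principal component carried 43.9% of the variance of log2 CPM and placed embryo libraries apart from larval ones. The second carried 18.5% and placed GFP-positive cells below GFP-negative cells at each stage. Replicates correlated across genes at 0.92 to 0.99 in all groups except whole L1 animals, whose 2 libraries correlated at 0.89. On the deposited rlog values that pair correlated at 0.91.

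**Figure D1:**
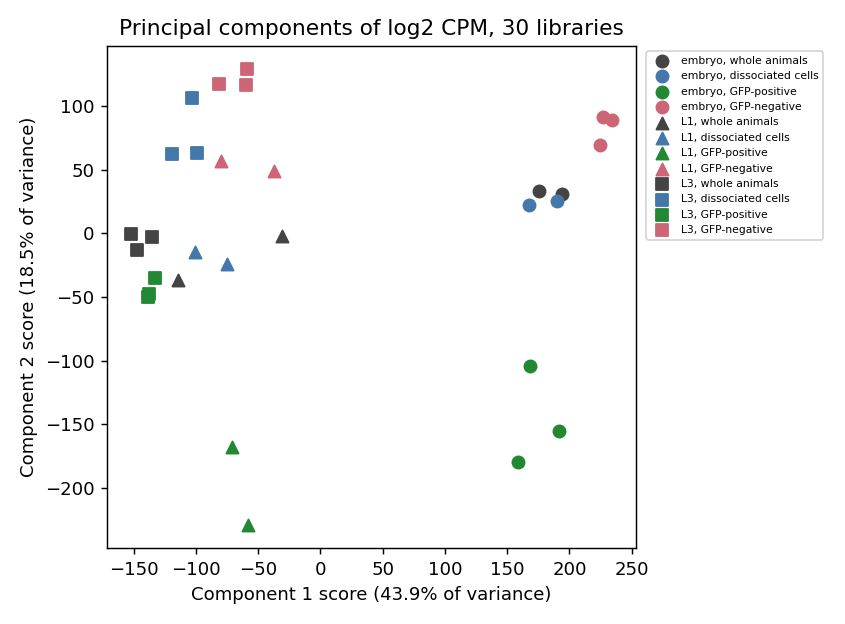
Scores of the 30 libraries on the first (x axis) and second (y axis) principal components of log2 CPM, in arbitrary score units, with 1 point per library, stages by shape and fractions by color. Embryo libraries lie at the right, and GFP-positive libraries lie below the GFP-negative libraries of their stage.

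The sort comparisons asked which transcripts were more abundant in GFP-positive than in GFP-negative cells. In embryo 3144 genes were higher and 4369 lower in GFP-positive cells. In L1 3219 were higher and 2281 lower, and in L3 3144 were higher and 3178 lower. The genes called higher had median log2 fold changes of 3.36 in embryo, 3.22 in L1 and 2.65 in L3. The genes called lower had medians of -1.74, -3.12 and -1.37. In the embryo sort the median over all tested genes was -0.55, and relative to it 3144 called genes were at least 2-fold higher and 2497 at least 2-fold lower. Higher genes made up 41.8% of embryo calls under TMM and 31.5% when libraries were scaled by their totals alone. With only the compared groups in the fit, 4138 genes were called in embryo, 72.4% of them higher, and 3450 in L1. In L1 the count was 3531 without GFP-positive replicate 1, and 3018 without the HiSeq X-ten libraries.

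Among single genes of the embryo sort, row 1871 had a log2 fold change of 11.28 ± 1.12 (SE) with an edgeR adjusted p of 2.58e-08. Its level was 954 ± 264 CPM (SD, n = 3) in GFP-positive and 0.388 ± 0.534 CPM (SD, n = 3) in GFP-negative cells. Row 5325 followed with 10.82 ± 0.84 (SE). The same row 1871 was 7.01 ± 1.02 (SE) higher in the L3 sort. The lowest values were -3.42 ± 0.9 (SE) for row 5419 and -3.37 ± 0.66 (SE) for row 15438, whose levels varied widely between replicates. One gene, row 10212, singled out after its values were seen, took 14.5% of the counts of embryo GFP-positive replicate 1 (95% Wilson interval 14.5 to 14.5%, counting error only). In the other embryo GFP-positive libraries it took 1.58% and 1.05%.

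**Figure D2:**
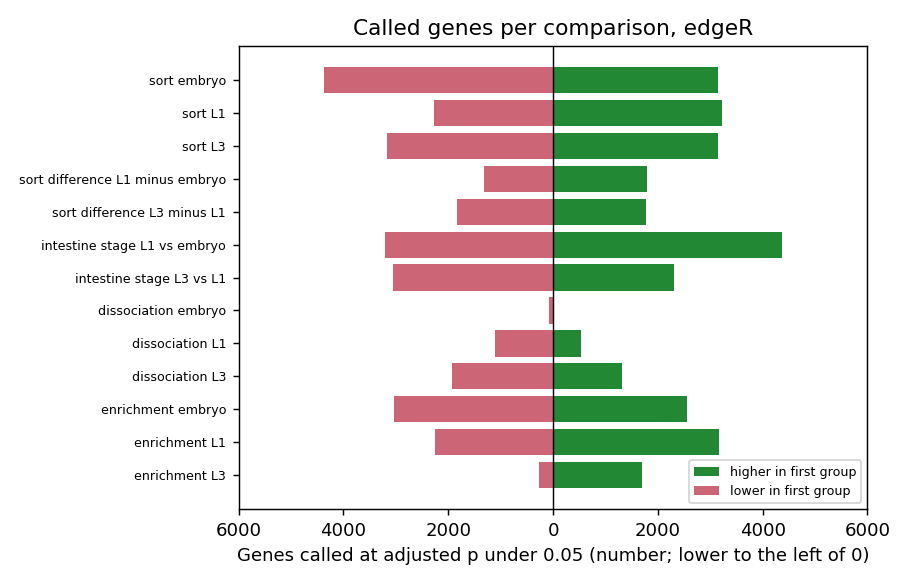
Number of genes (x axis) called at an edgeR adjusted p under 0.05 in each of the 13 comparisons (y axis), with genes higher in the group named first to the right of 0 and genes lower to the left. The embryo sort had 3144 higher and 4369 lower genes, and embryo dissociation had 22 and 69.

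Lists of genes enriched in GFP-positive cells overlapped between stages, whose sorts have no library in common. Embryo and L1 shared 1897 higher genes, against 604 for independent lists. L1 and L3 shared 2192 against 604, and embryo and L3 shared 1935 against 590. All these calls came from 1 fit to all libraries. With only the compared groups in the fit, the shared higher genes numbered 1470 against 450, 1730 against 468 and 1753 against 613, in the same order. At all 3 stages 1648 genes were higher, which was 32.1% of the 5131 genes higher at any stage and compared with 113 for independent lists, while 2403 genes (46.8%) were higher at exactly 1 stage. The count at all 3 stages ran from 1365 to 1675 when each library was left out in turn. Genes lower in GFP-positive cells were shared less evenly. Embryo and L3 shared 1577 against 829, and embryo and L1 981 against 595, while L1 and L3 shared 280 against 433. The last overlap turned to an excess without L1 GFP-positive replicate 3, at 888 against 598, with limma voom, at 568 against 397, and with only the compared groups in the fit, at 309 against 292. It was 11 against 61 with a minimum fold of 2 in glmTreat, 484 against 666 without embryo GFP-positive replicate 1 and 163 against 364 without L3 GFP-positive replicate 2. Compared with 113 for independent lists, 152 genes were lower at all 3 stages. That count was 624 without L1 GFP-positive replicate 3, 262 without embryo GFP-positive replicate 1, 250 without L1 GFP-negative replicate 3 and 94 without L3 GFP-positive replicate 2. By setting it was 1 with glmTreat, 59 with only the compared groups in the fit, 230 with DESeq2, 252 without the gene with the largest share and 265 with limma voom.

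The higher set from the other stages was measured in each stage's sort. In embryo its 2192 genes had a median log2 fold change of 3.46, against -0.76 for all other genes, with 1648 called higher and 48 lower. In L1 the 1935 genes had a median of 4.01, with 1648 higher and 18 lower. In L3 the 1897 genes had a median of 3.34, with 1648 higher and 4 lower. By the way the sets were formed, these 1648 are the shared GFP-positive genes each time. That count therefore adds nothing to the overlap above. With an estimated correlation the camera adjusted p was 2.55e-05 in embryo, 3.09e-05 in L1 and 2.21e-05 in L3. The lower set had smaller medians of -1.29 in embryo, -0.12 in L1 and -0.36 in L3, against -0.54, 0 and 0.17 for all other genes. Its camera calls were lost with an estimated correlation, at adjusted p = 0.15, 0.641 and 0.581. By fry, which does not compare the set with other genes, the embryo set passed with an adjusted p of 2.82e-06, and the L1 and L3 sets did not, at 0.293 and 0.226. In L1 its median was 0.21 without the HiSeq X-ten libraries, 0 without GFP-positive replicate 1, -0.7 without GFP-positive replicate 3, and -0.06 and -0.51 without GFP-negative replicates 1 and 3. In L3 it was -0.6 without GFP-positive replicate 1 and -0.22 without replicate 2. The L1 and L3 medians were -0.31 and -0.55 with limma voom and -0.28 and -0.2 with DESeq2.

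The share of counts in the higher set was larger in every GFP-positive library than in any GFP-negative library of its stage. GFP-positive cells gave 19.4 ± 1.4% (SD, n = 3) in embryo, 29 ± 1.1% (SD, n = 2) in L1 and 15.8 ± 0.29% (SD, n = 3) in L3. GFP-negative cells gave 7.62 ± 0.2% (SD, n = 3), 3.99 ± 0.021% (SD, n = 2) and 3.08 ± 0.25% (SD, n = 3). The genes of the set differ between stages, so these shares are compared within a stage.

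**Figure D3:**
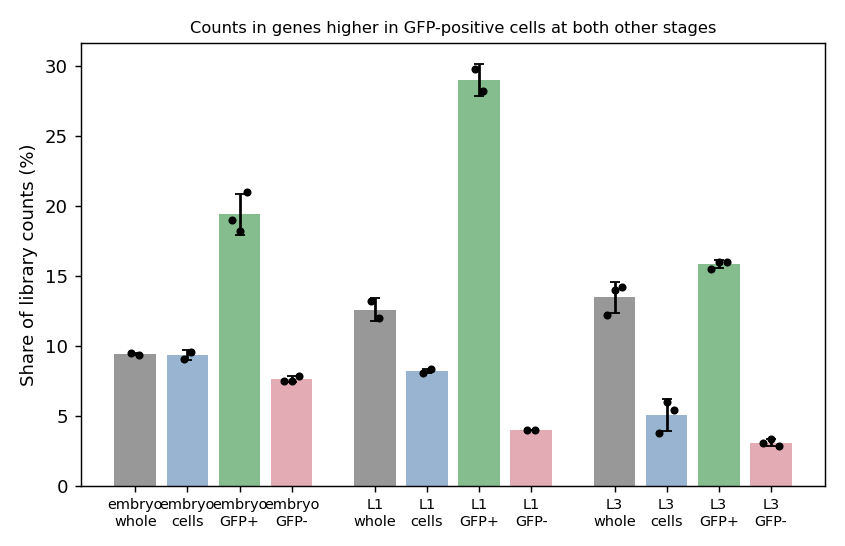
Percent of each library's counts (y axis) in the genes called higher in GFP-positive cells at both other stages, by stage and fraction (x axis), where bars are means, error bars are SD and points are libraries. In L3, dissociated cells averaged 5.05% and whole animals 13.5%.

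The difference of the sort effect between stages was tested directly. Between L1 and embryo 3113 genes differed, and between L3 and L1 3609. Of the 1897 genes higher in both embryo and L1, 403 also differed in the size of the effect, as did 225 of the 2192 higher in both L1 and L3. Among the shared GFP-positive genes, 164 had a larger and 204 a smaller effect in L1 than in embryo. From L1 to L3 the effect was larger for 5 and smaller for 179. Positive differences made up 57.6% of the L1 minus embryo calls under TMM and 47.6% under RLE scaling, and 49.1% and 64.1% of the L3 minus L1 calls. The counts among the shared GFP-positive genes were taken under TMM only. The L3 minus L1 count was 1488 without L1 GFP-negative replicate 3, 2237 without L1 GFP-positive replicate 3 and 2291 without L3 GFP-negative replicate 2. The L1 minus embryo count was 1910 without L1 GFP-negative replicate 3 and 1998 without L1 GFP-positive replicate 1. Without the HiSeq X-ten libraries the counts were 2178 and 1907.

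GFP-positive cells were compared between stages. From embryo to L1 4374 genes were higher and 3204 lower, with medians of 2.96 and -2.31 on the log2 scale. From L1 to L3 2316 were higher and 3053 lower, with medians of 3.46 and -1.65. Of the shared GFP-positive genes 833 were higher and 185 lower in L1 than in embryo. In L3 14 were higher and 821 lower than in L1, with a median log2 fold change of -1.41. The L3 against L1 count was 1878 without L1 GFP-positive replicate 1 and 2126 without the HiSeq X-ten libraries. Its lower genes numbered 1569 without L1 GFP-positive replicate 3 and 1433 without L3 GFP-positive replicate 3. The genes lower in L1 than in embryo numbered 2032 without L1 GFP-positive replicate 1. Higher genes made up 43.1% of the L3 against L1 calls under TMM and 69.7% with library totals alone. The median over all tested genes moved from -0.25 to 0.17 between these scalings. The counts and median of the shared GFP-positive genes were taken under TMM only.

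The dissociation comparisons asked how unsorted cells differed from whole animals. Per the labels, embryos had 20 min of chitinase and 5 min of pronase E before a syringe needle, and larvae 2 min of SDS-DTT and 30 min of pronase E before a dounce pestle. Stage and protocol therefore cannot be told apart in any comparison of dissociated or sorted cells between embryo and larvae. In embryo 22 genes were higher and 69 lower in dissociated cells, and in L3 1316 were higher and 1926 lower. In L3 the 1897 genes of the higher set had a median log2 fold change of -1.77, against 0.16 for all other genes, and 1052 of them were lower and 12 higher. The adjusted p with an estimated correlation was 0.000165. In embryo the set's median was -0.04, with 1 gene higher and 3 lower, and an adjusted p of 0.93 with an estimated correlation. In L1 its median was -0.55, with 123 lower and 3 higher, and an adjusted p of 0.19 with an estimated correlation and 0.0271 by fry. Higher genes were 40.6% of L3 calls under TMM and 58.6% with library totals alone, and 24.2% and 11.3% of embryo calls.

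In L1 528 genes were higher and 1115 lower in dissociated cells. Of the 1115, 867 (77.8%) were over 2-fold higher in whole L1 replicate 3 than in whole L1 replicate 1. That library entered the comparison, so calling lower genes favours such genes. In whole embryos 86.4% of the 1115 were over 2-fold higher than in dissociated L1 cells, against 31% of all genes. The same dissociated L1 libraries entered the calling of the 1115, which favours a high share here too. Neither share therefore settles what set the lower calls, and they cannot be assigned to dissociation alone. The count of called genes depended on single libraries. It was 99 without whole L1 replicate 3, 154 without dissociated L1 replicate 1 and 646 without dissociated L1 replicate 3. With only the 4 compared libraries in the edgeR fit no gene passed, with 2862 genes at an unadjusted p under 0.05, and 277 passed with limma voom and 3215 with DESeq2 on all libraries. The embryo count was 4 without dissociated replicate 1, 6 without whole replicate 2 and 261 without dissociated replicate 2. The L3 count was 1814 without whole replicate 1, 1925 without whole replicate 2, 2131 without dissociated replicate 1 and 1832 without dissociated replicate 3.

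The enrichment comparisons set GFP-positive cells against unsorted dissociated cells of the same stage. Embryo GFP-positive replicate 3 has no unsorted library of its number here. In embryo 2566 genes were higher and 3028 lower, in L1 3168 and 2245, and in L3 1704 and 261. The higher set had medians of 2.16 in embryo, 2.82 in L1 and 2.46 in L3, with 1365, 1539 and 1322 of its genes called higher. The adjusted p with an estimated correlation was 0.000324 in embryo, 0.000269 in L1 and 1.22e-06 in L3. Higher genes made up 45.9% of calls in embryo, 58.5% in L1 and 86.7% in L3 under TMM, and 30.4%, 32.9% and 75.7% with library totals alone. The L1 count was 1259 without the HiSeq X-ten libraries, 2094 without GFP-positive replicate 1 and 2654 without dissociated replicate 3. Of the L1 genes called higher, 1827 and 1997 were counted without dissociated replicate 1 and GFP-positive replicate 3. The embryo count was 3599 without dissociated replicate 2, and 1271 genes were higher without dissociated replicate 1. The L3 count was 950 without dissociated replicate 1. The 261 lower L3 genes numbered 70, 492 and 82 without dissociated replicates 1, 2 and 3 and 99 without GFP-positive replicate 2. By setting they numbered 2 with glmTreat, 28 at an adjusted p under 0.01, 147 with only the compared groups in the fit, 402 with the replicate block, 507 with library totals, 759 with DESeq2 and 989 with limma voom.

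**Figure D4:**
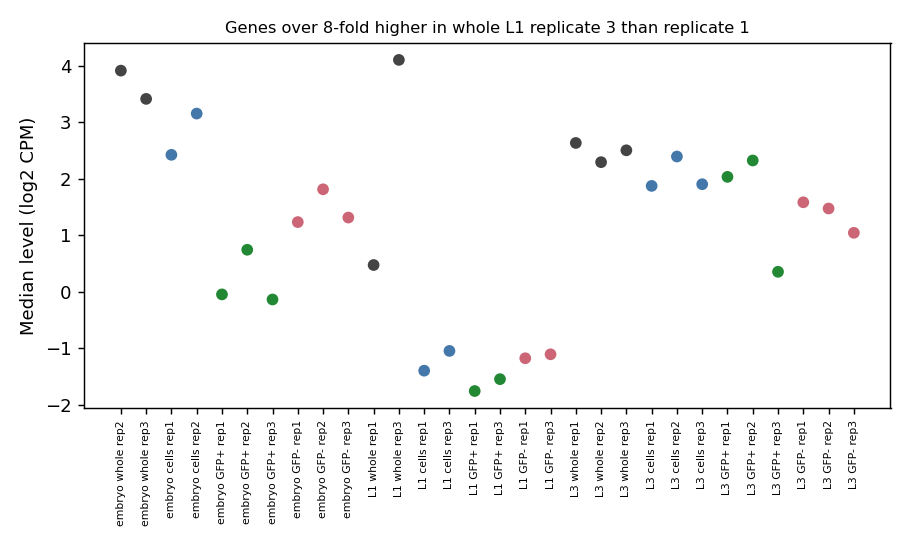
Median log2 CPM (y axis) in each library (x axis) of the 634 genes over 8-fold higher in whole L1 replicate 3 than in whole L1 replicate 1, with 1 point per library colored by fraction. The genes were chosen for the gap between the whole L1 libraries, at 0.47 and 4.1, and their medians in the whole embryo libraries were 3.91 and 3.41.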

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

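The gene sets, the tests of stage differences in dissociation and the test of GFP-positive L3 cells against whole animals were chosen after the result was seen. The tests of depth and scaling were written before their own values were seen. Their criterion was set from the unthinned L3 median, so it was not fixed before the data were examined. Some genes were called with opposite sort effects at neighbouring stages. The difference was called by edgeR for each of them, which choosing genes with opposite calls makes nearly certain, so it adds no support. In embryo against L1, 134 genes were higher and then lower in GFP-positive cells, and 170 were lower and then higher, fewer than the 428 and 839 of independent lists. In L1 against L3 the counts were 64 and 163, against 610 and 428. With each library left out in turn these 4 counts ran from 93 to 171, from 79 to 189, from 19 to 74 and from 72 to 214. The lowest values came without L1 GFP-positive replicate 1, except the 19, which came without L1 GFP-negative replicate 3. The count of 170 was also 98 without L1 GFP-negative replicate 3, and 109 and 111 without whole L3 replicates 2 and 3. It also fell by over 1.5 times without embryo GFP-positive replicate 3 or whole L3 replicate 1. The count of 163 was also 90 without L3 GFP-positive replicate 3, and 87 and 94 without L3 GFP-negative replicates 2 and 3. The count of 64 fell by over 1.5 times without any 1 of many libraries, such as to 24, 29 and 23 without each L3 GFP-negative library. No explanation was tested for these genes.

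The effect of dissociation on the shared GFP-positive genes differed between L3 and each other stage. The median difference was -1.29 for L3 minus L1 (fry adjusted p 0.000756, camera with an estimated correlation 0.00562) and -1.89 for L3 minus embryo (3.27e-05 and 0.000402), while -0.59 for L1 minus embryo did not pass (0.101 and 0.241). Both differences from embryo coincide with another dissociation protocol, while L1 and L3 had the same protocol. When each library was left out in turn the medians ran from -1.53 to -1.02 and from -2.07 to -1.61. Thinning all libraries to 1 depth left the L3 median of the higher set at -1.74. Totals already overlapped before thinning, at 20537830 to 25494842 counts in whole L3 animals and 17941198 to 24406261 in dissociated L3 cells. Thinning therefore had little depth difference to remove and could not test depth as the cause. Scaling moves all genes alike, yet the set's median minus that of all other genes was -1.92, so scaling alone is no account of it. A lower recovery of intestinal cells or their RNA during L3 dissociation may contribute. From whole L3 animals to GFP-positive L3 cells the set had a median of 0.37 that did not pass (fry adjusted p 0.0517, camera with an estimated correlation 0.113), against 2.08 in embryo and 2.06 in L1, which did. Sorting itself enriched these genes, by a median of 2.46 over unsorted L3 cells. A loss as large as the -1.77 in unsorted L3 cells could therefore still leave a value over 0. The comparison with whole animals thus cannot tell whether sorted L3 cells also lost such RNA. The stage difference between 0.37, 2.08 and 2.06 was not tested. A change of the intestine with stage also stays open and was not tested.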

How the results depend on the processing

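Most alternatives were fixed before the data were examined, and the deposited size factors, the CPM filter, thinning and removal of 1 gene were chosen after seeing the data. Of the counts of called genes under alternatives, 179 stayed within 1.5 times the main count and 72 did not. Of the set medians 271 moved by less than the spread between replicates, 20 by more, and 3 reversed. The filter removed only 4 genes and glmTreat leaves medians as they are, so neither is counted here where it tested nothing. The causes of the shifts below were not tested, except that higher thresholds call fewer genes by construction.

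With a minimum fold of 2 in glmTreat the sort counts were 3328 in embryo, 3605 in L1 and 2551 in L3, the sort differences 1189 and 756, and the stage comparisons 4672 and 2198. Dissociation gave 4, 614 and 818, and enrichment 2712, 2823 and 903. At an adjusted p under 0.01 the embryo sort had 4607 calls, the sort differences 1350 and 1021, and L3 against L1 2844. Dissociation had 19, 556 and 1410, and enrichment 3038, 2810 and 1142. With only the compared groups in the fit the sorts had 4138 in embryo and 3450 in L1, the sort differences 1137 and 2153, and the stage comparisons 4892 and 2331. Dissociation had 0 in L1 and 6377 in L3, and enrichment 2941 in embryo and 3573 in L1. The higher set's embryo sort median was then 3.94. Of the genes tested in both fits, 3864 embryo sort calls and 3370 L1 sort calls were shared with the same sign.

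With limma voom the sort differences gave 1726 and 2017, dissociation 467, 277 and 7890, and L3 enrichment 3088. With DESeq2 embryo dissociation gave 767, L1 dissociation 3215 and L3 enrichment 3038. Embryo dissociation gave 141 with RLE factors, 141 with library totals and 143 with the deposited size factors. Without the HiSeq X-ten libraries the L1 sort gave 3018 with a higher-set median of 3.59, the sort differences 1907 and 2178, L3 against L1 2126 and L1 enrichment 1259. The lower-set medians reversed to 0.21 in the L1 sort and 0.28 in L1 enrichment, and the latter to 0.15 without dissociated L1 replicate 1.

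With the replicate block, embryo dissociation gave 28 calls, though its groups share only 1 replicate number. The block changed no other total of called genes by over 1.5 times, though the lower genes of L3 enrichment rose from 261 to 402. Sort calls with it were 8340 in embryo, 5959 in L1 and 6898 in L3, against 7513, 5500 and 6322 in the main fit. For GFP-positive cells compared between stages the block was the replicate number alone. The labels state no link between replicates of different stages. In L3 not every pair correlated over 0.1 for dissociation or enrichment.

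Leaving out each library in turn gave 6240 to 7642 calls in the embryo sort, 3531 to 5533 in L1 and 5288 to 5785 in L3. The sort differences ran from 1910 to 3059 and from 1488 to 3366, and the stage comparisons from 5825 to 7631 and from 1878 to 4566. Dissociation ran from 4 to 261 in embryo, 99 to 2355 in L1 and 1814 to 2840 in L3. Enrichment ran from 3599 to 5915, 2094 to 4695 and 950 to 1885. The higher-set sort medians ran from 2.97 to 3.76, 3.56 to 3.97 and 3.13 to 3.56, and its dissociation medians from -0.13 to 0.13, -0.67 to -0.25 and -1.91 to -1.53. Where this leaves 1 library in a group, that library is assumed to vary like the other groups.

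The real groups were set against the other splits of the same 6 libraries. For 1 of 10 splits, the real one, the count was as large in each of the 4 comparisons that allow it. The counts were 7513 in the embryo sort against at most 491, 6322 in the L3 sort against 0, 3242 in L3 dissociation against 0 and 1965 in L3 enrichment against 1. With 10 splits the share cannot fall under 0.05. In the other splits the real difference lies within the groups and widens their spread. Their low counts therefore do not measure how many genes would be called by chance. Among embryo sort splits that part all 3 pairs the highest other count was 1. Thinning every library to the smallest total, 10994387 counts, gave 6435 calls in the L3 sort against 6322.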

Other observations

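The tests of whole L1 replicate 3 and of L3 against L1 depletion were chosen after the result was seen. The other tests of L3 depletion were written before their own values were seen, though thinning was chosen after seeing the data. Whole L1 replicate 3 differed from replicate 1 by over 8-fold in 634 genes that were higher and 286 that were lower. The same replicate contrast in the other L1 fractions correlated with it across genes at 0.1 at most, which argues against a batch shared by all L1 fractions, though not against one of this library alone. Whole L1 replicate 3 correlated at 0.89 with the other whole L1 library and at 0.87 at most with a library of another group. For each of the 11 other groups its highest correlation lay below the lowest replicate correlation of that group, at 0.92 to 0.98. This argues against a typical library of another group under this label, though not against a mixture or an outlying library. The criterion was reworded after its values were seen. The contrast correlated across genes at 0.68 with the difference between whole embryos and dissociated L1 cells, and at 0.28 with that for L3. Embryos or other stages among the whole L1 animals of replicate 3 may therefore have contributed, as a hypothesis found and tested on these data.

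In the all-library fit only 166 genes were at least 8-fold lower in GFP-positive L3 cells, against 536 in embryo and 1222 in L1. The 100 most depleted genes were chosen in the other pairs and measured in the pair left out. They came from genes with a mean level of at least 20 CPM in GFP-negative cells. L1 had 2 pairs, so the choice there rested on a single other pair. Each value is relative to the median of all genes over that level, unlike the 8-fold counts. The sort medians over all tested genes were -0.55 in embryo and 0.13 in L3, so this reference can change how stages compare. The 100 genes had median log2 differences of -3.95, -1.85 and -1.62 in the L3 pairs. They had -4.87 and -4.41 in the L1 pairs and -0.91, -1.27 and -2.12 in the embryo pairs. By this measure depletion was not shallower in L3 than in embryo, and the L3 mean of -2.47 was shallower than the -4.64 of L1, but exact permutation tests, two-sided, gave p = 0.3 and 0.2 (adjusted over both, 0.3), and neither can go below 0.1. The gap between L3 and L1 was 2.17 and was 2.13 after thinning, which argues against depth as its whole cause, while against embryo the thinned difference was -0.95, so that depth could not be tested for a pattern that comparison lacks. Strongly and moderately expressed genes differed by -0.02 in L3, but the pairs varied too much to tell whether reads from other cells set a common limit, and a change with stage was not tested.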
